A study of Mus musculus with 2 samples.

How the data were processed

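Single-cell RNA libraries of the mouse hippocampus were made after papain dissociation with the 10x protocol, per the labels' protocols, and there were 2 libraries, 1 control (saline) and 1 EMF_AuNPs (gold nanoparticles with an electromagnetic field). The groups were taken from the treatment label of each sample. The labels give an age of 6 months and 3 weeks of exposure, while the titles call the brain aged. The protocol leaves open whether the control mice were also placed between the coils, and the number of animals per library, the substrain, the injected amount per mouse and the days of dissection are not given in the sources used here. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised, and the authors made them with Cell Ranger 3.0.2 and STAR on mm10, per the submitters' processing notes. The annotation and the version of STAR are not given in the sources used here.

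The matrices list 24130 gene symbols, of which 123 are joint symbols of several genes that were kept as given, and 0 mitochondrially encoded genes. The planned filter on the mitochondrial share, its stricter alternative and the list of mitochondrially encoded genes could therefore not be run. The deposited barcodes numbered 21583 in the control and 7003 in the EMF_AuNPs library, and the lowest UMI totals were 500 and 501. Cells with at least 500 UMIs and 250 genes were kept, which left out 158 and 7 barcodes. Doublets were called in each library by the nearest-neighbour method with simulated doublets, as in Scrublet, in an implementation of its own, with an expected rate of 0.8% per 1000 cells and the threshold at the minimum between the modes of the simulated scores. The calls were 1592 control cells (7.43%, expected 17.1%) and 159 EMF_AuNPs cells (2.27%, expected 5.60%). With 6 clusters in which over 50% of cells were called, 1882 and 231 cells were removed, and doublets of like cells and those below the threshold remain.

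UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave a shared-neighbour graph of both libraries, which was clustered with the Leiden method at resolution 1 and seed 1. No integration step was applied, so a cluster held mostly by 1 library may be that library and not a cell type. Clusters with at least 3 markers of 2 classes were clustered again. A cluster was named by the class with at least 3 of its markers among the top 50 genes by fold over the median cluster, with 10 CPM added. Names were withheld where the top 10 genes went against them or where a median UMI count far below the library's (under 1/3) went with no marker among the top 10. The list of 196 marker genes for 24 classes was fixed beforehand, and 5 of these markers were missing from the matrices. Names are "like" names rebuilt from these markers, since no annotation of the cells by the authors was used here. The clusters held mostly by 1 library are named beside the comparisons within a class.

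UMIs were summed per library and class and divided by the class total to give CPM, UMIs relative to a class total set to 1e6, in the 12 classes with at least 50 cells in each library. The log2 ratio is that of EMF_AuNPs over control with 1 CPM added to both. Its interval is the exact conditional binomial interval of the ratio of CPM with nothing added, so at low counts it need not be centred on the printed ratio. Intervals of CPM are exact Poisson intervals, those of shares are Clopper-Pearson intervals, those of differences of shares are Newcombe intervals and those of list medians are order-statistic intervals over the genes. Those of differences of marker sums use a normal approximation from the UMI counts, which is rough at few UMIs. A count of 0 allows up to 3 counts. With 1 library per group no test, p-value or standard error between replicates was computed, cells were not used as replicates, and a ratio of at least 1.5-fold is written as higher or lower. Scaling was not centred for single genes, and the median log2 ratio of all genes was 0.16 in astrocyte-like, -0.11 in Cajal-Retzius-like, 0.10 in ependymal-like, 0.35 in choroid plexus-like and 0.40 in red blood cell-like cells and within 0.1 of 0 in the other compared classes.

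Named genes followed a rule. Eligible genes had at least 100 UMIs over both libraries, a mean of at least 20 CPM, and at least 20% of the highest mean CPM of any compared class. This keeps out much of the free RNA of other compared classes. Excitatory neuron-like cells and interneurons were not compared, so their free RNA can pass. The 6 highest and 6 lowest ratios were named in the 4 classes with the most cells in the smaller library (microglia-, oligodendrocyte-, astrocyte- and endothelial-like) and in Cajal-Retzius-like cells, with the 2 eligible members of the largest absolute ratio of each list that fits the class. Kat2a, Dcx, Sox2, Nes, Neurod1, Bdnf, Mki67 and Gfap were named wherever detected, and their values in classes with few UMIs of them are left out of the text. Some genes that the rule names are not reported here. The rule, the markers, the 28 gene lists, the designs and the alternative settings listed first below were fixed before the data were examined. The assignment of lists to classes was written down only after the list values had been seen, and so was the choice of Nnt, Wdfy1, Yipf4, Camk2a and Morf4l1,Morf4l1-ps1 as genes shared by classes. List medians use members with at least 20 summed UMIs, relative to the median of all genes of the class, and are placed among 10000 random lists of the same size drawn from 20 bins of expression. Of the list genes outside the mitochondrial list, 3 were missing.

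Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, which left out 3565 of 19543 control and 1379 of 6765 EMF_AuNPs cells. They are given beside those of microglia-like and endothelial-like cells, as background of free RNA for genes these classes should lack. That does not hold for Kat2a, and it may not hold for Mki67 in microglia-like cells, some of which may divide. Coordinates are those of the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, in which 23172 of the 24130 symbols (96.0%) were found. They were matched by symbol, and the annotation is not that of the authors.

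The ratio, interval and list steps were tested on simulated counts for the genes of each class, with 200 genes given known folds. These counts were Poisson draws of the class sums, so the summing of cells and the clumping of UMIs in single cells were not tested. The coverage and the rates below hold for such counts only. The intervals covered the true ratio for 95.5% of these genes in endothelial-like (6452 eligible genes), 96.5% in astrocyte-like (6113), 94.5% in oligodendrocyte-like (5786), 93.5% in microglia-like (6229) and 98.0% in Cajal-Retzius-like cells (730). Genes given 4-fold were called higher or lower rightly in 100% of cases in these 5 classes. Genes given 2-fold were called rightly in 97.0% in endothelial-like, 98.5% in astrocyte-like, 100% in oligodendrocyte-like, 97.0% in microglia-like and 95.5% in Cajal-Retzius-like cells. At 1.5-fold, the threshold itself, these shares were 49.3%, 47.8%, 52.2%, 53.7% and 47.8%. Unchanged genes passed 1.5-fold in 0.144%, 0.135%, 0.0358%, 0.946% and 4.75% of cases. A simulated list shifted by 0.8 had medians of 0.80, 0.81, 0.79, 0.86 and 0.74.

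The alternative settings were a minimum of 1000 UMIs per cell, doublet calls kept, resolution 2, each library clustered on its own, thinning to 1000 UMIs, microglia-like cells left out of the denominator, a pseudocount of 10 CPM, a minimum of 100 summed UMIs, scaling by the median ratio over genes or by the TMM factors of edgeR, and thinning to 500 UMIs or none. After the data had been seen, 6 more were added. They were the subtraction of the median ratio over the other classes (for lists and for genes), ratios without the cell with the most UMIs of a gene in each library, unnamed cells counted by the leading class of their cluster, red blood cell-like cells left out of the denominator, and cells of at least 1000 UMIs named as in the full clustering. Cells and classes were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and leidenalg 0.10.2, figures were drawn with matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 gave the TMM factors.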

Results

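Gene expression was measured in single cells of the hippocampus of male C57BL/6 mice, given as 6 months old in the labels, in 2 libraries with 1 library per group. The control library came from mice given saline, and the EMF_AuNPs library from mice whose hippocampus was injected with gold nanoparticles and which were exposed to an electromagnetic field between Helmholtz coils for 3 weeks. The title of the series names neurogenesis in the living brain as the subject, so the genes of neural stem cells and new neurons and the make-up of the tissue were compared first. The control library held 21583 barcodes with 51091452 UMIs and a median of 1904 UMIs per barcode, and the EMF_AuNPs library held 7003 barcodes with 19544686 UMIs and a median of 2310. After the filters and the removal of doublet calls, 19543 control cells and 6765 EMF_AuNPs cells were analysed, with median depths of 1806 and 2248 UMIs. With 1 library per group no difference has a replicate check and none was tested. Intervals are 95% intervals that cover counting error only, except that those of list medians cover the spread between the genes of a list. Values in brackets after a correlation are the lowest and the highest over classes or pairs of classes. All of them describe these 2 libraries, not the treatments.

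Oligodendrocyte-like cells, which make myelin, were 28.9% (28.3 to 29.5) of control cells and 15.6% (14.7 to 16.4) of EMF_AuNPs cells, a difference of -13.3 percentage points (-14.4 to -12.3). Microglia-like cells, the resident macrophages of the brain, were 17.9% of control and 13.3% of EMF_AuNPs cells, a difference of -4.60 points (-5.56 to -3.62). Red blood cell-like cells were 0.670% (0.561 to 0.795) of control and 5.94% (5.39 to 6.53) of EMF_AuNPs cells. Border macrophage-like cells, which line vessels and meninges, were 0.977% and 1.88%, and smooth muscle-like cells were 1.30% and 2.38%. T or NK cell-like cells were 0.169% (33 cells) and 0.532% (36 cells).

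Astrocyte-like cells made up 17.5% of control and 17.1% of EMF_AuNPs cells, a difference of -0.423 points (-1.45 to 0.634) that depended on which cells took the name. Endothelial-like cells were 16.1% and 18.0%, pericyte-like cells 3.99% and 4.79%, and choroid plexus-like cells 2.62% and 2.94%. Ependymal-like cells were 0.916% and 1.24%, Cajal-Retzius-like cells 0.988% and 1.20%, fibroblast-like cells 1.06% and 1.03%, and excitatory neuron-like cells 0.977% and 0.695%. Oligodendrocyte precursor-like cells were 0.435% and 0.384%, monocyte or neutrophil-like cells 0.420% and 0.325%, and B cell-like cells 0.409% and 0.207%. Cells in clusters left without a name were 4.40% of control and 12.2% of EMF_AuNPs cells, and most of these EMF_AuNPs cells (702 of 822) lay in cluster 5, whose median was 780 UMIs. Astrocyte was the leading class of cluster 5, with 2 markers among its top 50 genes where the rule asked for 3. The astrocyte-like difference was 7.54 points (6.35 to 8.75) with unnamed cells counted by leading class and 9.12 with each library clustered on its own. The share of barcodes below 1000 UMIs was 16.9% in the control and 19.7% in the EMF_AuNPs library, a depth gap that can set shares. When cells below 1000 UMIs were left out before clustering, the differences were -7.32 points for microglia-like, 8.06 for astrocyte-like (4.23 with the names of the full clustering), 4.47 for endothelial-like, 1.46 for border macrophage-like and -0.221 for Cajal-Retzius-like cells. When every cell was thinned to 1000 UMIs before clustering, the differences were 2.17 points for red blood cell-like and 8.45 for astrocyte-like cells.

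**Figure D1:**
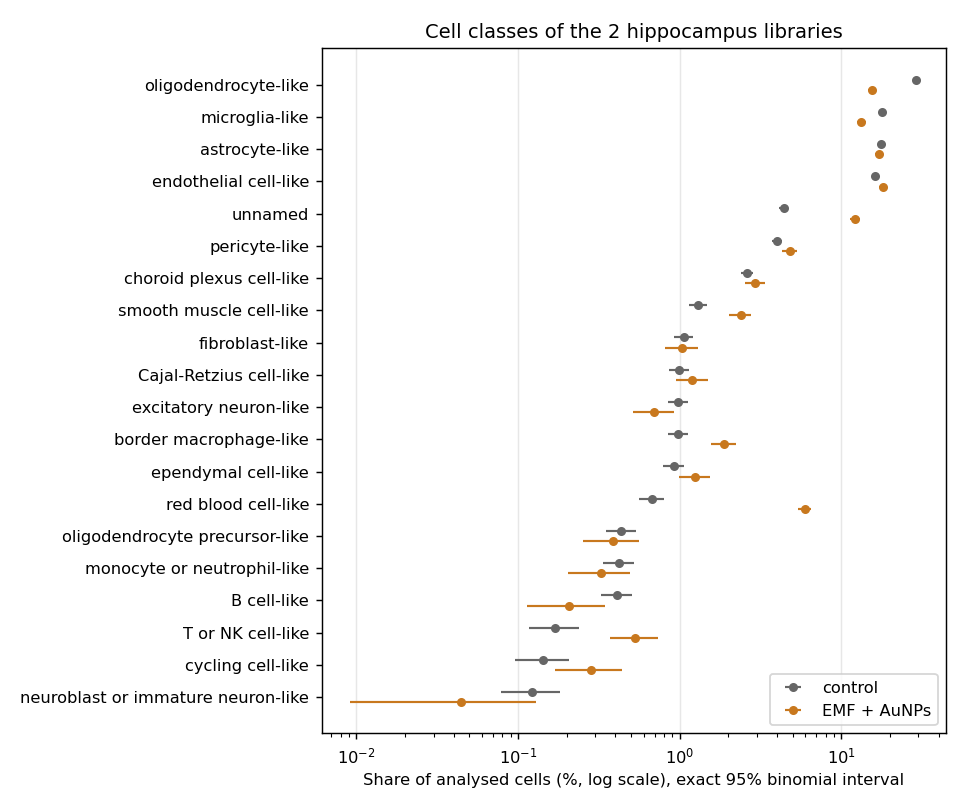
Share of analysed cells in each named class, in percent, for the control and the EMF_AuNPs library, with exact 95% binomial intervals that cover counting error only. The oligodendrocyte-like share was 28.9% in control and 15.6% in EMF_AuNPs cells, and the red blood cell-like share was 0.670% and 5.94%.

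Neuroblast-like cells, the immature neurons marked by doublecortin, were 24 of 19543 control cells (0.123%, 0.0787 to 0.183) and 3 of 6765 EMF_AuNPs cells (0.0443%, 0.00915 to 0.130). The difference of -0.0785 points had an interval from -0.145 to 0.0165, so no difference was detectable at this depth. Cycling-like cells were 28 control cells (0.143%) and 19 EMF_AuNPs cells (0.281%), a difference of 0.138 points (0.0182 to 0.301). This difference was -0.114 points when cells below 1000 UMIs were left out before clustering and -0.0634 points when every cell was thinned first. The cycling-like cells fell into a cluster of 21 and 9 cells, which Sox11 and Igfbpl1 of immature neurons also led, and a cluster of 7 and 10 cells, which the chemokine genes Ccl4 and Ccl12 also led. No cluster met the marker rule for granule neurons, interneurons, radial glia-like stem cells, intermediate progenitors or committed oligodendrocyte precursors, which does not show that such cells were absent. Of the Eomes UMIs in control cells, 28 lay in 9 cycling-like and 9 in 3 neuroblast-like cells. In EMF_AuNPs these classes, of 19 and 3 cells, held 0 Eomes UMIs, and 5 lay in 3 T or NK cell-like cells. Unnamed cluster 14, with 355 control and 111 EMF_AuNPs cells, had excitatory neuron as its leading and granule neuron as its next class.

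Over whole libraries, Dcx, which encodes the microtubule protein doublecortin of new neurons (mm10 chromosome X, 143855842 to 143933311, minus strand), had 70 UMIs in the control and 25 in the EMF_AuNPs library. These were 1.37 CPM (1.07 to 1.73) and 1.28 CPM (0.828 to 1.89). Neurod1, a transcription factor of neuronal differentiation (chromosome 2, 79452521 to 79456751, minus strand), was lower in EMF_AuNPs, with 3.72 CPM (3.21 to 4.29) against 0.563 CPM (0.281 to 1.01). Of the Neurod1 UMIs in control cells, 61 lay in unnamed and 41 in neuroblast-like cells, and both populations, of 822 and 3 cells, held 0 in EMF_AuNPs. The unnamed cells of the libraries are not alike. Of the 822 EMF_AuNPs cells 702 lay in cluster 5, which astrocyte led, and cluster 14, which excitatory neuron led, held 355 control and 111 EMF_AuNPs cells. Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361, minus strand), was higher, with 1.86 CPM (1.504 to 2.27) against 5.63 CPM (4.63 to 6.78). Its UMIs lay in cycling-like cells (43 in 13 control cells and 56 in 10 EMF_AuNPs cells) and in oligodendrocyte-like cells (18 and 12), among other classes. Of the rest, 13 lay in 2 control monocyte or neutrophil-like cells and 15 in 2 EMF_AuNPs oligodendrocyte precursor-like cells. Microglia-like cells held 3 Mki67 UMIs in 3 control cells and 10 in 4 EMF_AuNPs cells. Sox11 of immature neurons was 13.4 and 16.6 CPM, Eomes of intermediate progenitors 0.822 and 0.409 CPM (42 and 8 UMIs), and the stem cell genes Sox2 and Nes differed by 0.26 and -0.25 on the log2 scale. These 2 values do not single out stem cells. In control, Nes had 2589 UMIs in endothelial-like, 525 in pericyte-like and 46 in astrocyte-like cells, and Sox2 had 2932 in astrocyte-like and 2481 in oligodendrocyte-like cells. The library values of Sox11 and Eomes do not single out new neurons or their progenitors either. Sox11 had 173 UMIs in control and 16 in EMF_AuNPs neuroblast-like cells, 130 and 105 in astrocyte-like and 70 and 71 in cycling-like cells. Of the Eomes UMIs in EMF_AuNPs, 5 lay in T or NK cell-like cells. The neurotrophin gene Bdnf was 4.60 and 2.20 CPM.

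Kat2a, which encodes a histone acetyltransferase (chromosome 11, 100704746 to 100712465, minus strand), had 582 UMIs in the control and 309 in the EMF_AuNPs library, or 11.4 CPM (10.5 to 12.4) and 15.8 CPM (14.1 to 17.7), a log2 ratio of 0.44 that is below 1.5-fold. Within classes its log2 ratio was 0.48 (-0.21 to 1.21) in microglia-like, 0.32 (-0.22 to 0.90) in astrocyte-like, 0.31 (-0.18 to 0.83) in endothelial-like and 0.13 (-0.35 to 0.62) in oligodendrocyte-like cells, and each of these intervals held 0. Of cells thinned to 1000 UMIs, 1.25% of control and 1.62% of EMF_AuNPs cells had a Kat2a UMI, a difference of 0.370 points (0.0146 to 0.776). With doublet calls kept it was 0.314 points (-0.0328 to 0.711), an interval that held 0. In astrocyte-like cells the thinned difference was 0.309 points (-0.444 to 1.30), but 1.11 points (0.291 to 2.12) when cells below 1000 UMIs were left out before clustering. The thinned shares were 1.01% and 1.495% in microglia-like and 1.42% and 2.25% in endothelial-like cells, and no class known to lack this widely used gene was at hand as background. Without thinning the shares over all cells were 2.46% and 4.20%, at median depths of 1806 and 2248 UMIs.

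Dcx was found in 0.156% of thinned control and 0.186% of thinned EMF_AuNPs cells, a difference of 0.0292 points (-0.0836 to 0.193). The background in microglia-like cells was 0 of 2965, which allows 0.101%, and 0.166% of 602 cells, and in endothelial-like cells it was 0 of 2530, which allows 0.119%, and 0 of 1110, which allows 0.270%. Neurod1 was found in 0.325% and 0.0371% of thinned cells, a difference of -0.288 points (-0.393 to -0.163), against 0.202% and 0% in microglia-like and 0.119% and 0% in endothelial-like cells. Sox11 was found in 1.06% and 1.30%, Mki67 in 0.150% and 0.278%, and Eomes in 0.0438% and 0.0371%, and the interval of each of these differences held 0, but with cells thinned to 500 UMIs the Mki67 difference was 0.164 points (0.0565 to 0.319). Sox11 was found in 0.540% and 0.332% of thinned microglia-like cells and in 0.356% and 0.360% of thinned endothelial-like cells, and Mki67 in 0.0337% and 0.498% of microglia-like cells (0.136% and 1.17% when cells below 1000 UMIs were left out before clustering). Mki67 in endothelial-like cells and Eomes in both classes were found in 0 thinned cells, which allows 0.101% and 0.498% in microglia-like and 0.119% and 0.270% in endothelial-like cells. Of thinned astrocyte-like cells, 2.88% in control and 3.46% in EMF_AuNPs had a Sox11 UMI. Without thinning, Dcx was found in 0.271% and 0.325% of cells, Sox11 in 1.88% and 2.85%, Neurod1 in 0.645% and 0.163%, Mki67 in 0.261% and 0.621% and Eomes in 0.0768% and 0.0887%.

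In microglia-like cells, the genes of MHC class I antigen presentation and those of disease-associated microglia lay higher in EMF_AuNPs than the other genes of the class. All list medians are log2 ratios of EMF_AuNPs over control relative to the median of all genes of the class. Of 11 class I genes 7 lay at least 1.5-fold above the class median and 0 below it, with a list median of 0.79 (0.45 to 1.46). H2-D1 was 231 CPM (219 to 244) in control and 619 CPM (581 to 659) in EMF_AuNPs cells, a log2 ratio of 1.42 (1.30 to 1.54), and H2-K1 was 309 and 748 CPM, a log2 ratio of 1.27 (1.17 to 1.38). Both encode heavy chains that present peptides to T cells, both lie on chromosome 17 (35262730 to 35267499 on the plus strand and 33996017 to 34000347 on the minus strand), and reads shared with close relatives of this family make the single values uncertain. Of 24 genes of disease-associated microglia 13 lay above and 0 below, with a list median of 0.67 (0.28 to 1.39). Lpl, the lipoprotein lipase gene (chromosome 8, 68880491 to 68907448, plus strand), had the highest ratio under the rule for named genes, with 11.3 CPM (8.78 to 14.4) and 85.0 CPM (71.4 to 101) and a log2 ratio of 2.80, from 66 UMIs in 42 control cells and 137 UMIs in 34 EMF_AuNPs cells. The receptor kinase gene Axl was 15.8 and 43.4 CPM. Among 10000 random lists matched on size and expression, the medians of both lists stood at percentile 100, which describes these 2 libraries and is no test.

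Interferon response genes had a median of 0.66 (0.24 to 0.99) with 11 of 21 members above and 2 below, among them Lgals3bp at 0.66 and the interferon transcription factor gene Irf9 at -0.77. Lysosome and phagocytosis genes had a median of 0.49 with 9 of 23 above, led by the proteases Lgmn at 1.22 and Ctsc at 1.01. Inflammatory cytokines and NF-kB targets had a median of 0.29 (0.04 to 0.43) with 4 of 19 above, led by the receptor gene Tlr2 (37.7 and 96.8 CPM) and the cytokine gene Il1a (40.8 and 83.1 CPM). Homeostatic microglia genes had a median of 0.17 (-0.13 to 0.44), although Gpr34 (1.00) was higher. The 6 MHC class II genes had a median of 1.25 (0.35 to 2.77), and H2-DMb1 at 0.69 and H2-DMa at 0.32 were the members expressed enough in the class to be named. Immediate early and dissociation genes had a median of 0.29 (-0.13 to 0.55) with Klf4 at -1.15 and Socs3 at 0.91. The median of histone acetyltransferases was -0.17 (-0.62 to 0.46), at percentile 12.9 of the random lists, with Crebbp at -1.13 and Kat6a at -0.85. Ccl5, C5ar1 and Cd48, all genes of immune signalling, had log2 ratios of 1.81, 1.65 and 1.55, Cept1 of 1.74 and Yipf4 of 1.66. The lowest ratios were those of Kif13b (-1.75), Paxbp1 (-1.74), Casc4 (-1.70), Tnfrsf13b (-1.68), Zc3h6 (-1.68) and Dhx8 (-1.66).

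Microglia-like cells fell into clusters 1 (2866 control and 461 EMF_AuNPs cells), 9 (428 and 428) and 21 (203 and 10), and Ccl3 and Ccl4 were among the leading genes of cluster 1. Once the median ratio of the same gene over the other classes was subtracted, the signs of Gpr34 (-0.88), Lgmn (-0.45), Ctsc (-0.06), Cept1 (-0.03), H2-DMb1 (-0.22) and the homeostatic (-0.51) and inflammatory (-0.31) lists turned, while H2-D1 was 0.75, H2-K1 0.47 and Lpl 2.65. The median of disease-associated microglia genes was then 0.27, that of lysosome genes 0.040, that of MHC class I 0.48 and that of interferon genes 0.41. The homeostatic microglia genes were also higher in EMF_AuNPs cells of other classes, with list medians of 1.05 in oligodendrocyte-like, 0.84 in endothelial-like (0.14 with doublet calls kept) and 1.46 in Cajal-Retzius-like cells.

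In oligodendrocyte-like cells, genes of myelin differed little as a group, with a list median of 0.08 (-0.15 to 0.45) over 22 genes, of which 2 lay at least 1.5-fold above the class median and 0 below it, at percentile 94.005 of the random lists. Those 2 were the tight junction gene Cldn11 (chromosome 3, 31149920 to 31164324, plus strand), at 1492 and 3018 CPM with a log2 ratio of 1.02 (0.98 to 1.05), and the transferrin gene Trf at 0.76 (0.74 to 0.78). Genes of MHC class I had a median of 0.73 (0.36 to 1.05) with 6 of 9 above, and interferon response genes 0.72 (0.30 to 0.89) with 13 of 21 above, and with a pseudocount of 10 CPM these medians were 0.30 and 0.26. In the same cells homeostatic microglia genes, markers of another cell type, had a median of 1.05 with 13 of 16 above, and inflammatory genes 0.92 with 8 of 10 above (0.31 with the pseudocount of 10 CPM). Cholesterol biosynthesis genes had a median of 0.32 with 5 of 20 above and 1 below, led by Msmo1 (79.7 and 181 CPM) and Fdps (0.99). Heat shock protein genes had a median of -0.44 (-0.65 to 0.04) with 4 of 14 below, led by the endoplasmic reticulum chaperone gene Hspa5 at 398 and 217 CPM and by Dnaja1 at -0.61.

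Immediate early genes had a median of 0.51 in these cells with 9 of 22 above. The 2 eligible members with the largest absolute log2 ratio were Rhob (0.51) and Arc (-0.46). Of the interferon genes, Ifi27 was 0.48 and Xaf1 -0.18. Histone acetyltransferases had a median of -0.04 (-0.49 to 0.25), at percentile 34.3, with Kat6a at -0.81 and Crebbp at -0.57. The highest ratios were those of Wdfy1 (2.06, with 16.9 and 73.4 CPM), Yipf4 (1.58), Cept1 (1.41), Ptp4a1 (1.31), Rab4a (1.25) and Ppp1cb (1.21). The lowest was that of Camk2a, a calcium-dependent kinase gene of neurons (chromosome 18, 60925618 to 60988152, plus strand), at 53.4 and 13.04 CPM with a log2 ratio of -1.96 (-2.49 to -1.61), followed by Ddx23 (-1.77), Cplx2 (-1.50), Heca (-1.44), Nfe2l1 (-1.43) and Zfp106 (-1.43). As a gene of neurons, Camk2a may be free RNA in these cells, which was not tested. Of the control cells 5086 lay in cluster 0 and 560 in cluster 4, and of the EMF_AuNPs cells 136 and 916. Relative to the other classes the signs of Yipf4 (-0.08), Cept1 (-0.35), Ppp1cb (-0.12) and Msmo1 (-0.22) turned, and the medians were 0.34 for MHC class I, 0.33 for interferon, 0.079 for cholesterol, -0.13 for heat shock, 0.52 for homeostatic microglia and 0.44 for inflammatory genes.

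In astrocyte-like cells, genes of cholesterol biosynthesis and glycolysis lay higher in EMF_AuNPs than the other genes of the class, with medians of 0.44 (0.08 to 0.72) and 0.39 (0.25 to 0.52). These lists were not particular to this class. Cholesterol medians were 0.37 in microglia-, 0.32 in oligodendrocyte-, 0.23 in endothelial- and 0.15 in Cajal-Retzius-like cells, and glycolysis medians there were 0.38, 0.18, 0.20 and 0.66. The astrocyte-like class had median depths per cell of 1356 UMIs in control and 2773 in EMF_AuNPs. Its shallow cluster 6 (median 663 UMIs) held 915 control and 172 EMF_AuNPs cells. Shallow cluster 5, which astrocyte led and which held 702 EMF_AuNPs cells, stayed unnamed, so depth and library cannot be told apart here. Of 20 cholesterol genes 7 lay at least 1.5-fold above the class median and 1 below it, led by Msmo1 (266 and 639 CPM) and Dhcr7 (1.01), and of 16 glycolysis genes 3 lay above and 1 below, led by Aldoc and Pfkl, both at 0.92. Astrocyte homeostatic genes had a median of 0.27 (-0.14 to 0.44), with 3 of 20 above, among them Glul, the glutamine synthetase gene (chromosome 1, 153899944 to 153909723, plus strand), at 1476 and 3036 CPM with a log2 ratio of 1.04 (1.00 to 1.08), and Cpe at 1.06. Reactive astrocyte genes had a median of 0.29 (0.02 to 0.64) with 5 of 17 above and 2 below. The intermediate filament gene Gfap was 622 CPM (601 to 644) and 948 CPM (914 to 982), a log2 ratio of 0.61, and the complement gene C4b was 108 and 188 CPM.

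Neural stem cell and neurogenesis genes had a median of 0.13 (-0.86 to 0.44) in astrocyte-like cells, with 3 of 19 above and 5 below. Hopx, a gene of quiescent stem cells and astrocytes, was 311 and 764 CPM, and Sox2 had a log2 ratio of 0.10. Growth factor genes had a median of -0.10, with Ptn at -1.11 and Vegfa at 0.48. Oxidative stress genes and metallothioneins had a median of 0.11 with 5 of 24 above, led by catalase, Cat, at 42.9 and 123 CPM and by the glutathione reductase gene Gsr at 1.01. Interferon genes had a median of 0.51 (0.04 to 0.77) with 9 of 21 above, Ifit3 at 0.83 and Lgals3bp at 0.76 among them, but with a minimum of 100 UMIs per gene that median was -0.015. Homeostatic microglia genes had a median of 0.43 (-0.14 to 1.08) in these cells. Histone acetyltransferases had a median of -0.10, at percentile 19.7, with Kat2b at 0.81 and Crebbp at -0.73. The highest ratio was that of Cxcl10 (2.92), where 85 of 119 EMF_AuNPs UMIs lay in 1 cell, and it was 1.99 without the cell with the most UMIs in each library. Ppp1cb (2.07), Nxt2 (1.995), Tollip (1.88) and Tspan12 (1.87) followed, and the lowest were Sst (-1.75), Pisd-ps1 (-1.71), E130102H24Rik (-1.70), Nrgn (-1.67), Eno1,Eno1b (-1.64) and Capn15 (-1.63). Sst and Nrgn are marker genes of neurons and may be free RNA in these cells, which was not tested. The control cells lay mostly in clusters 3 (2485) and 6 (915) and the EMF_AuNPs cells in cluster 7 (870), against 115, 172 and 25 cells of the other library, and the median log2 ratio of all genes of the class was 0.16. Relative to the other classes the signs of C4b (-0.02) and Msmo1 (-0.13) turned, and the medians were 0.23 for cholesterol, 0.17 for glycolysis, 0.15 for interferon, 0.14 for astrocyte homeostatic, 0.018 for reactive and -0.21 for homeostatic microglia genes.

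In endothelial-like cells, the genes of the blood-brain barrier showed no common direction, with a list median of -0.07 (-0.36 to 0.38) and 2 of 23 members at least 1.5-fold above and 1 below the class median, at percentile 51.7. The tight junction gene Ocln was 74.7 and 134 CPM, and Cav1, the caveolin gene, was 197 and 315 CPM. Among the highest ratios were those of the chemokine receptor gene Ackr3 (11.4 and 48.0 CPM), Ankrd37 (39.6 and 152 CPM) and Adm, which encodes the vasodilator adrenomedullin (9.81 and 34.6 CPM). The log2 ratio of Ackr3 was 1.98 here and had a median of 1.83 over the other classes, so it was not particular to endothelial-like cells. For Ankrd37 these values were 1.91 and 0.86, and Adm had enough UMIs in too few other classes for such a median. Growth factor genes had a median of -0.28 (-0.81 to -0.0040) with 4 of 12 below and 0 above, among them Ptn at -1.13 and Hbegf at -0.71.

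MHC class I genes had a median of 0.11 (-0.21 to 0.27) in endothelial-like cells, with 0 of 12 above or below, Tapbp at 0.37 and H2-T23 at 0.34. Interferon genes had a median of 0.18 with 4 of 23 above, Ifit1 at 0.70 among them, beside 0.84 for homeostatic microglia genes (9 of 16 above), a median that was 0.14 with doublet calls kept. Immediate early genes had a median of -0.03 with 5 of 24 below, led by Fos (1238 and 623 CPM) and Gadd45b (-0.84). Oxidative stress genes had a median of 0.07, with Cat at 0.74 and the thioredoxin reductase gene Txnrd1 at -1.30 (62.2 and 24.6 CPM). Over the other classes Txnrd1 had a median log2 ratio of -1.06. Histone acetyltransferases had a median of -0.02, at percentile 37.0, with Crebbp at -0.69 and Taf1 at -0.56. Nes, which had more UMIs in this class than in any other in both libraries, was 410 and 277 CPM. Wdfy1 (2.01) and Yipf4 (1.78) were also among the highest, and Abhd2 (-1.54), Camk2a (-1.54), Morf4l1,Morf4l1-ps1 (-1.37), 1810022K09Rik (-1.36) and Gzf1 (-1.34) were among the lowest. Camk2a, a gene of neurons, may be free RNA here, which was not tested. All 204 UMIs of Dcpp1, the gene with the highest ratio of all, lay in 1 EMF_AuNPs cell. Cluster 2 held 2334 control and 989 EMF_AuNPs cells and cluster 8.0 held 355 and 5, and haemoglobin genes were among the leading genes of clusters 8.1 (75 and 154 cells) and 8.2 (148 and 18). Relative to the other classes the signs of Ocln (-0.11), Cav1 (-0.03), Ifit1 (-0.13), Cat (-0.02), Crebbp (0.0061) and Morf4l1,Morf4l1-ps1 (0.24) turned, and the medians of MHC class I, interferon and growth factor genes were -0.50, -0.18 and -0.12.

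Cajal-Retzius-like cells, early-born neurons that secrete reelin, were the only neuronal class with at least 50 cells in each library, in cluster 16 with 193 control and 81 EMF_AuNPs cells and 374801 and 124396 UMIs. Synaptic and neuronal activity genes had a median of 0.06 (-0.38 to 0.89) with 4 of 13 at least 1.5-fold above the class median and 1 below it, at percentile 69.8. Syt1, the calcium sensor gene of synaptic vesicles, was 819 CPM (730 to 916) and 378 CPM (278 to 502), and Gria2, a glutamate receptor subunit gene, was 419 CPM (356 to 490) and 723 CPM (582 to 889). Genes of calcium channels and calcium signalling had a median of -0.28 (-0.65 to 0.49) with 3 of 10 below and 1 above, with the channel subunit gene Cacna2d1 at -0.76. Neurogenesis genes had a median of 0.41 (-0.48 to 1.08) over 12 members, with Stmn2 at -0.89 and Stmn1 at -0.58, and the 5 histone acetyltransferase genes measured had -0.59 (-0.87 to 0.48), at percentile 6.35. Gpr37l1 (1.49), Ctsl (1.40), Laptm4a (1.37), Rhob (1.24), Htra1 (1.21) and Tubb2b (1.17) had the highest ratios. Markers of other cell types also lay higher in this class, with medians of 0.86 for astrocyte homeostatic genes (13 of 20 above) and 1.46 for homeostatic microglia genes (14 of 14), and lysosome genes had a median of 1.35 (15 of 17). Morf4l1,Morf4l1-ps1 (-2.37), Skp1a (-1.61), Map1a (-1.52), Csnk2a1 (-1.50), Rab11fip2 (-1.49) and Smarca5 (-1.48) had the lowest ratios. Dcx had 0 and 3 UMIs and Kat2a 5 and 5 in this class, too few to compare. The median of all genes was -0.11 in this class and the edgeR scaling moved its ratios by 0.12. Relative to the other classes Syt1 was 0.26, the synaptic list 1.01, the neurogenesis list 0.21, histone acetyltransferases 0.095 and lysosome genes 0.77.

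**Figure D2:**
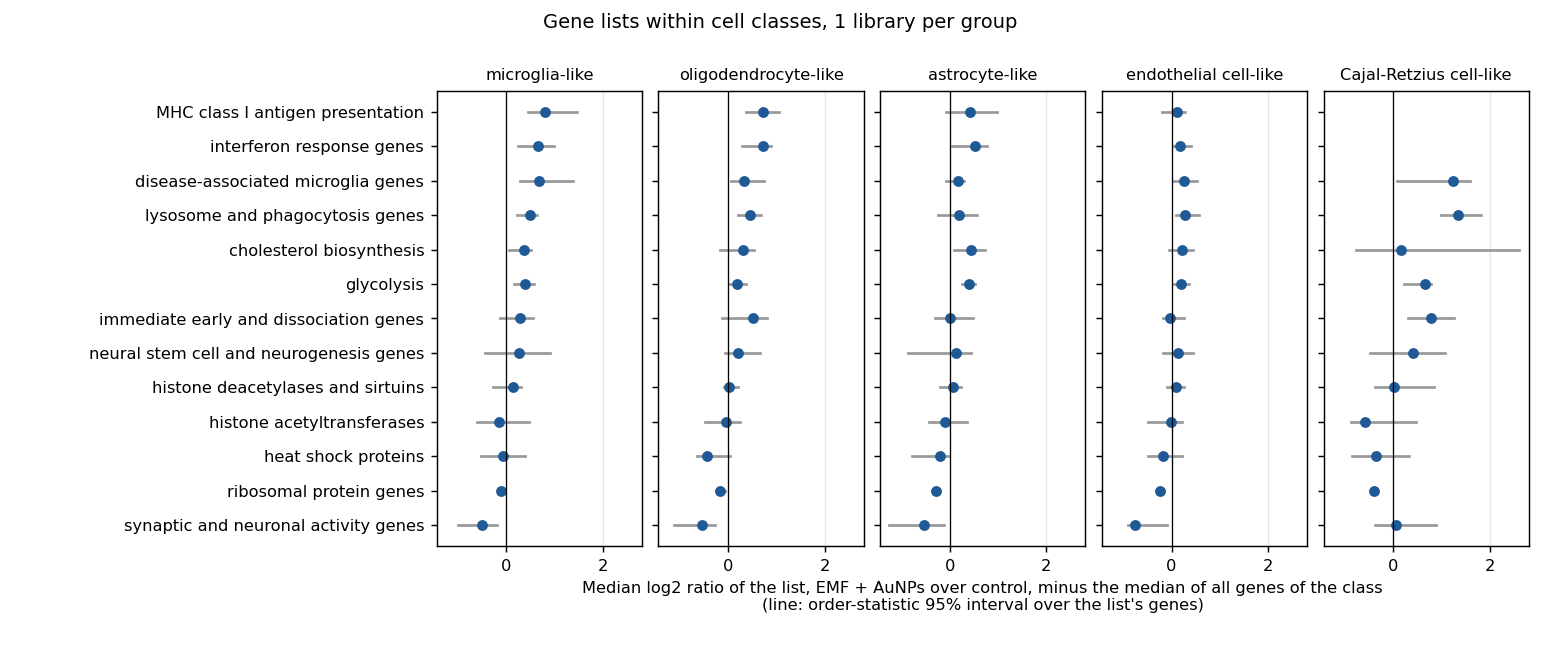
Median log2 ratio of EMF_AuNPs over control of selected gene lists in 5 cell classes, relative to the median of all genes of the class. A list with fewer than 5 measured genes in a class is not drawn there. Homeostatic microglia, inflammatory, myelin and blood-brain barrier genes are among the lists left out. MHC class I genes stood at 0.79 in microglia-like, 0.73 in oligodendrocyte-like and 0.11 in endothelial-like cells.

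Genes shared by many cell types also differed between the libraries in the same direction in several classes. Across 5944 genes, the log2 ratios of 7 classes correlated with a median Pearson r of 0.620 over 21 pairs of classes (0.488 to 0.779), a correlation across genes, which are not independent replicates. Named after their values were seen, Nnt, a mitochondrial transhydrogenase gene, was higher in EMF_AuNPs in 7 of 7 classes that had enough UMIs, with log2 ratios from 1.22 to 1.91. This gene is partly deleted in the C57BL/6J substrain, and the substrain of the mice of either library is not given in the sources used here. Wdfy1 (chromosome 1, 79702262 to 79776143, minus strand) was higher in 10 of 10 classes, from 0.73 to 2.50, and Yipf4 (chromosome 17, 74489493 to 74500277, plus strand) in 12 of 12, from 0.65 to 1.98. Camk2a, which may be free RNA of neurons in glial and vascular classes, was below control in 11 of 11 classes, from -1.96 to -0.47, and Morf4l1,Morf4l1-ps1, a joint symbol of a gene and its pseudogene, in 12 of 12, from -2.37 to -1.14. Malat1, a long RNA kept in the nucleus, was 66507 CPM of the control and 50949 CPM of the EMF_AuNPs library.

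**Figure D3:**
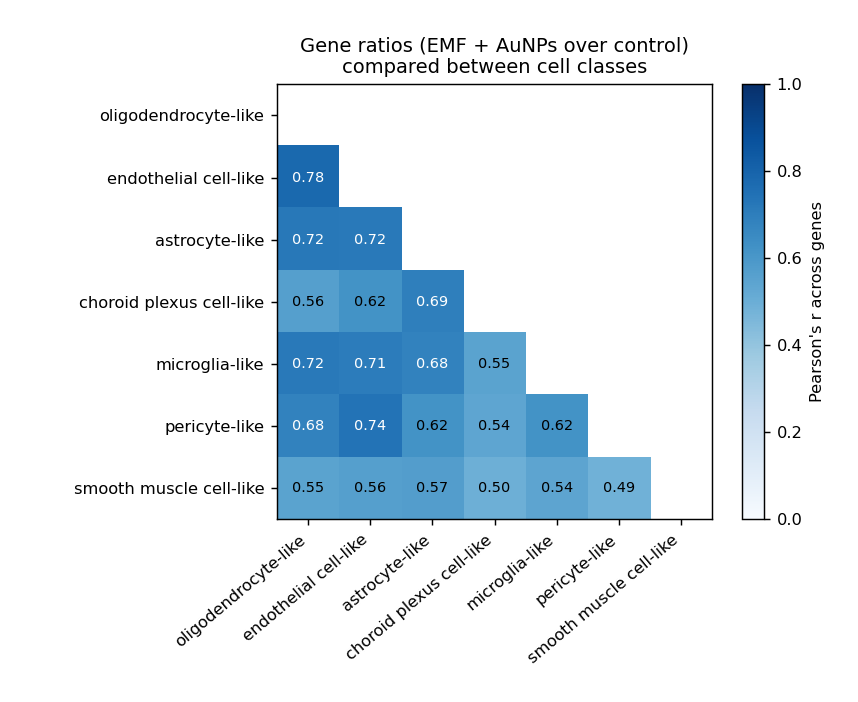
Pearson correlation across 5944 genes of the log2 ratio of EMF_AuNPs over control between each pair of 7 cell classes. The values of the 21 pairs lay between 0.488 and 0.779.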

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

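None of the differences in this part was tested, and the values were picked out after all classes had been computed. Irf9, a transcription factor gene of the interferon response, had a log2 ratio of EMF_AuNPs over control of 0.85 (0.36 to 1.55) in oligodendrocyte-like cells, from 74 and 38 UMIs, and of -0.77 (-1.41 to -0.24) in microglia-like cells, from 189 and 30 UMIs. It stood out because the ratios had opposite signs in the 2 classes, 1.62 apart, and the difference between them was not tested. Gria2, a glutamate receptor subunit gene, had a ratio of 0.79 (0.40 to 1.17) in Cajal-Retzius-like cells, from 157 and 90 UMIs, and of -0.59 (-0.99 to -0.25) in endothelial-like cells, from 240 and 84 UMIs. These opposite signs lie 1.38 apart, and that difference was not tested either.

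Cluster 5, which was left without a name and enters no comparison within a class, held 10.4% (9.66 to 11.1) of EMF_AuNPs cells and 2.41% (2.20 to 2.63) of control cells, more than in the control library. Its median depth was 780 UMIs.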

How the results depend on the processing

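The subtraction of the ratio over other classes, the ratios without the top cell, the counting of unnamed cells by leading class, the denominator without red blood cell-like cells and the classes of cells of at least 1000 UMIs are tests chosen after the data had been seen. No paired analysis was possible because each group has 1 library. Of the values under alternatives, 131 of shares stayed within the interval of the main value, 27 moved beyond it and 2 reversed, and for list medians these numbers were 918, 37 and 12. A reversal is a change of sign where the interval excluded 0 (and, for genes, the ratio was at least 1.5-fold), and any change of sign occurred in 16 values of shares, 62 of lists and 54 of genes. For named genes they were 1051, 188 and 18, and all 18 reversals came from the subtraction of other classes. For shares of cells with a UMI 19 stayed within the interval and 5 moved. List medians cannot move under the other scalings, which shift all genes of a class alike, and the minimum of 1000 UMIs cannot move the shares over all cells thinned to 1000 UMIs. The alternatives with a mitochondrial share of 10% were not run, as no such genes were in the matrices. There was no value for monocyte or neutrophil-like and neuroblast-like shares at the minimum of 1000 UMIs, for excitatory neuron-like cells after thinning, or for monocyte or neutrophil-, B cell-, neuroblast-, cycling-, excitatory neuron- and Cajal-Retzius-like cells with each library clustered on its own, where no EMF_AuNPs cluster took the name. The neuroblast-like share rested on 24 control and 3 EMF_AuNPs cells, and the interval of its difference held 0. Apart from denominators and the subtraction, which act by construction, the cause was not tested.

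Differences in share, in percentage points, were as follows. With a minimum of 1000 UMIs per cell, they were -7.32 for microglia-, 1.46 for border macrophage-, -14.9 for oligodendrocyte-, 8.06 for astrocyte-, -0.114 for cycling-, -0.221 for Cajal-Retzius- and 4.47 for endothelial-like cells. Among cells of at least 1000 UMIs named as in the full clustering, they were -7.38 for microglia-, 1.35 for border macrophage-, -14.7 for oligodendrocyte-, 4.23 for astrocyte-, -0.122 for Cajal-Retzius- and 4.77 for endothelial-like cells. With every cell thinned before clustering, they were -7.63 for microglia-, 1.40 for border macrophage-, -15.1 for oligodendrocyte-, 8.45 for astrocyte-, -0.0634 for cycling-, -0.301 for Cajal-Retzius-, 4.55 for endothelial- and 2.17 for red blood cell-like cells. At resolution 2 they were -15.0 for oligodendrocyte- and 0.779 for astrocyte-like cells. Astrocyte-like cells differed by 0.680 with doublet calls kept, by 9.12 with each library clustered on its own and by 7.54 with unnamed cells counted by leading class. With microglia-like cells left out of the denominator, the differences were -17.3 for oligodendrocyte-, -1.62 for astrocyte- and 6.04 for red blood cell-like cells. Of cells not thinned, the differences in share with a UMI were 0.970 for Sox11, -0.482 for Neurod1, 0.360 for Mki67 and 1.74 for Kat2a, and thinned to 500 UMIs that of Neurod1 was -0.135.

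List medians under the other settings were as follows. With doublet calls kept, blood-brain barrier genes were at 1.10 in Cajal-Retzius-like cells, and homeostatic microglia genes at 0.14, myelin genes at -0.38 and ribosomal genes at -0.14 in endothelial-like cells. With a minimum of 1000 UMIs per cell, myelin genes were at 0.61 and respiratory genes at -0.23 in astrocyte-like cells, and ribosomal genes at -0.28 in Cajal-Retzius-like cells. With cells thinned, myelin genes were at 0.36 in astrocyte- and 0.70 in microglia-like cells, and respiratory genes at 0.095 in Cajal-Retzius-like cells. With a minimum of 100 summed UMIs, glycolysis was at 0.80 and ribosomal genes at -0.25 in Cajal-Retzius-like cells, interferon genes at -0.015 in astrocyte-like cells and calcium genes at -0.0056 in endothelial-like cells. With a pseudocount of 10 CPM, MHC class I was at 0.30, interferon genes at 0.26 and synaptic genes at -0.27 in oligodendrocyte-like cells.

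Minus the ratio over other classes, medians in microglia-like cells were 0.27 for disease-associated, -0.51 for homeostatic microglia, -0.31 for inflammatory, 0.040 for lysosome, 0.19 for respiratory, 0.17 for ribosomal and -0.0059 for synaptic genes. In oligodendrocyte-like cells they were 0.34 for MHC class I, -0.14 for glycolysis, 0.52 for homeostatic microglia, 0.17 for lysosome, 0.047 for respiratory, 0.075 for ribosomal and -0.14 for synaptic genes. In astrocyte-like cells they were -0.20 for disease-associated, 0.17 for glycolysis, 0.0025 for heat shock, -0.21 for homeostatic microglia, 0.0088 for respiratory, 0.018 for reactive, -0.064 for ribosomal and -0.00037 for synaptic genes. In endothelial-like cells they were -0.50 for MHC class I, -0.11 for glycolysis, 0.075 for inflammatory, -0.18 for interferon, -0.019 for respiratory, -0.017 for ribosomal and 0.0044 for calcium genes. In Cajal-Retzius-like cells they were 0.77 for lysosome, -0.23 for ribosomal and 1.01 for synaptic genes. Single genes that reversed were C4b (-0.024) and Msmo1 (-0.13) in astrocyte-like cells, and Cat (-0.023), Cav1 (-0.031), Crebbp (0.0061), Ifit1 (-0.13), Morf4l1,Morf4l1-ps1 (0.24) and Ocln (-0.11) in endothelial-like cells. Further ones were Cept1 (-0.029), Ctsc (-0.058), Gpr34 (-0.88), H2-DMb1 (-0.22) and Lgmn (-0.45) in microglia-like cells. In oligodendrocyte-like cells they were Cept1 (-0.35), Msmo1 (-0.22), Ppp1cb (-0.12) and Yipf4 (-0.078), and in Cajal-Retzius-like cells Syt1 (0.26).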

Other observations

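In this part, the tests of a ratio shared by all classes and of T or NK cells for MHC class I, of red blood cells for the oligodendrocyte-like share and of MHC class I in pairs of classes were chosen only after the result was seen. Synaptic and neuronal activity genes lay lower in EMF_AuNPs in glial and vascular classes, which express few of them, with list medians of -0.75 (-0.90 to -0.10) in endothelial-like, -0.54 in astrocyte-like, -0.53 in oligodendrocyte-like and -0.51 in microglia-like cells. Of 21 members 14 lay at least 1.5-fold below the class median in endothelial-like cells and 0 above it. Ribosomal protein genes had medians of -0.39 in Cajal-Retzius-like, -0.29 in astrocyte-like, -0.24 in endothelial-like, -0.17 in oligodendrocyte-like and -0.12 in microglia-like cells. Nuclear-encoded respiratory chain genes had medians of -0.16 in endothelial-like and 0.020 in microglia-like cells. Myelin genes had a median of -0.44 in astrocyte-like cells and 0.85 in endothelial-like cells, and the latter was -0.38 with doublet calls kept, while the former was 0.61 at a minimum of 1000 UMIs per cell and 0.36 with cells thinned.

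Histone deacetylase and sirtuin genes had medians of 0.13 in microglia-like, 0.10 in endothelial-like, 0.07 in astrocyte-like and 0.02 in oligodendrocyte-like cells. Cell cycle genes had medians of 0.04 in microglia-like and 0.28 in astrocyte-like cells, and senescence and p53 target genes 0.27 and 0.18. Calcium channel and signalling genes had medians of -0.15 in microglia-like and -0.20 in astrocyte-like cells. The sex check genes were measured in both libraries of male mice, with Xist at 7 and 8 UMIs and Ddx3y at 75.1 and 116 CPM, and the 4 members with enough UMIs had a median of 0.54 in microglia-like cells. In border macrophage-like cells the MHC class II gene H2-Aa was 334 CPM in control and 3028 CPM in EMF_AuNPs. Within its cluster 17 it was 26.3 and 52.0 CPM and within cluster 22.1, which class II genes lead, 3588 and 9034 CPM, and cluster 22.1 held 13 of 191 control and 37 of 127 EMF_AuNPs cells.

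The gene ratios shared by the cell classes had a median r of 0.620 across genes. Gene length or GC content as the whole cause was argued against, since the median r was 0.603 (0.465 to 0.761) with both regressed out. Free RNA taken up by all classes stays open, since the median r of 0.663 (0.512 to 0.833) over 2701 genes within 3-fold between the classes decides nothing, as free RNA adds 1 profile to all classes, and the lower synaptic genes in glial and vascular classes go with it. A smaller nuclear share of RNA in the EMF_AuNPs cells cannot be told apart from other causes, since ratios between control cells of low and high Malat1 share correlated with the library ratios at 0.175 (0.137 to 0.203), between the values set for and against it. Differences between the libraries in animals, in their substrain (which can differ in Nnt), in dissection, library preparation or treatment may each give such a pattern, and with 1 library per group none of these was tested.

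The MHC class I genes of microglia-like cells had a list median of 0.79, and border macrophages among these cells were argued against, since the marker sum of border macrophages and T cells differed by -0.179% (-0.464 to 0.106) of its 6771 CPM in border macrophage-like cells. T or NK cells were argued against by their own markers, which summed to 15 UMIs in control and 3 in EMF_AuNPs, a difference of -0.0207% (-0.0923 to 0.0508) of their 3463 CPM in T or NK cell-like cells, although Ccl5 was higher at 1.81. A ratio shared by all classes stays open, because the median relative to the other classes was 0.48 (0.07 to 0.83), and against single classes it was 0.75 (0.17 to 1.24) for endothelial-like, 0.10 (0.01 to 0.89) for astrocyte-like and 0.07 (-0.31 to 0.26) for oligodendrocyte-like cells. Activation during dissociation stays open as well, with a class I median of 0.28 (0.06 to 0.69) between 1748 control microglia-like cells with more and 1749 with fewer immediate early UMIs, a split that moved the immediate early list by 1.60 against 0.29 between the libraries. A response of microglia to the particles or the field is a hypothesis that may fit as well and was not tested.

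The oligodendrocyte-like share differed by -13.3 percentage points. Red blood cells filling the EMF_AuNPs library were argued against as the whole cause by the shares themselves. The red blood cell-like share differed by only 5.27 points (4.72 to 5.87). Without red blood cell-like and unnamed cells the oligodendrocyte-like difference was -11.4 points (-12.7 to -10.2). That value follows from shares already seen and also drops the unnamed cells, so it adds no evidence of its own. Loss of shallow cells at the count threshold stays open, because cells below 500 UMIs are not in the matrices and the -14.7 points (-16.0 to -13.4) among cells of at least 1000 UMIs cannot show them. Of the oligodendrocyte-like cells kept, 229 of 5646 in control and 17 of 1052 in EMF_AuNPs lay below 1000 UMIs. Dissection of more or less white matter and uneven survival of cells in dissociation may set this share and were not tested, nor was the treatment.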
